A study of Mus musculus with 6 samples.

How the data were processed

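RNA was sequenced from OT-I CD8 T cells of mouse splenocytes that were stimulated with the SIINFEKL peptide for 48 h and treated with BiTS, BiTS(mut) or an isotype control, with 2 libraries in each of the 3 groups. The deposited values are raw counts per gene, 1 table per library, made by the authors. The submitters' processing notes name mm10 as the genome build and DESeq2 as a tool. The aligner, the counter, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. Per the file headers, each table lists the exon intervals of its genes, and all coordinates given here come from those tables.

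The tables held 49671 genes and 92 ERCC spike-in transcripts. Gene symbols were taken by identifier from GENCODE release M21, which held 49412 of the 49671 identifiers. Of these, 49375 lay on the same chromosome and 45177 had the same start and end as in the deposited tables. The 259 identifiers without a match held 0.013% of the counts. Total gene counts ran from 10813123 to 15239077 per library. A count of 3, the upper limit that a count of 0 allows, corresponded to 0.197 to 0.277 CPM. Intervals on shares of counts are 95% Wilson intervals and, like this limit, cover counting error only. Spike-in transcripts took 3.36% to 7.54% of all counts and were left out of the gene totals, the filter and the scaling.

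Counts were scaled by TMM, filtered with filterByExpr and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the 13996 genes that passed the filter. A gene was called at an adjusted p under 0.05. The design chosen before the data were examined fitted all 6 libraries with 1 coefficient per group and no block. The alternatives also chosen before the data were examined were a replicate block, DESeq2 1.42.0, limma-voom, RLE size factors, library totals alone, no filter on low counts, a CPM of at least 5 in at least 2 libraries, only the 4 libraries of the groups compared, a 2-fold threshold, and leaving out each library in turn. Combinations of the block with these choices, scaling to the spike-in transcripts, and leaving out a group of 6 genes around CT010467.1, the only one of them annotated as ribosomal RNA, were added after the data were seen.

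The block puts the libraries with title numbers 1 to 3 (isotype replicate 1, BiTS(mut) replicate 1 and BiTS replicate 1) in a first set and those with title numbers 4 to 6 (isotype replicate 4, BiTS(mut) replicate 2 and BiTS replicate 2) in a second set. This pairing comes from the title numbering. The labels do not say that a number marks a batch, and the library names number the isotype libraries 1 and 4 but the others 1 and 2. Across the 13996 genes, deviations from the group means correlated at 0.66, 0.74 and 0.73 between libraries of the same set. With 2 libraries per group the deviations mirror each other, so only these 3 correlations are distinct, and the evidence that the numbers pair the libraries comes from the data and not from a stated design. Between libraries, the chi-square per degree of freedom over genes was 4.29 to 10.02 within a set and 29.81 to 44.5 across sets. The evidence thus rests on 3 correlations over 0.1, which meets a rule of 3 or more pairs only on a generous reading. The blocked values are given beside the unblocked ones because the block was among the choices made before the data were examined, with 2 residual degrees of freedom in place of 3.

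Gene lists were fixed before the data were examined. Of 28 lists with 613 different genes, the 26 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. Fry tests whether a list's genes move, on balance, 1 way, and does not compare the list with other genes. Its mixed form tests for movement in either direction. The neutrophil and erythroid lists had 0 and 2 tested members and were not tested. The list lookup was by symbol, and Lilrb4a was among the members with no tested gene.

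Named genes followed a rule fixed before the data were examined. For each comparison it took the 10 largest increases and the 10 largest decreases among called genes with a mean CPM of at least 5 in the higher group, no overlap between the groups' libraries and a symbol that is not a gene-model name. It added up to 3 called members of each list with the smallest p, and 15 fixed genes whatever their result, and it allows some of these to be left out of the text. No gene was called without the block, so the rule was applied to the blocked fit, which was decided after that count was seen. Statements on how often named genes kept their call or sign cover every gene of the rule, named in the text or not. The results of 2 genes of the rule, each with a leave-one-out value of the opposite sign, are not reported here.

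The steps were tested on simulated counts with 200 genes changed by a log2 fold change of 0.5, 1 or 1.5, in the BiTS libraries, drawn with the means, library sizes and set differences of these libraries. Each gene's simulated set difference was the same in every group and its spread came from the blocked fit. These settings are what the block assumes, so the rates below favour the blocked fit. In BiTS against isotype, 198 changed genes were among the 13802 tested. Without the block 0 of 198 were recovered. With the block 72.7% were recovered, 49.1% at 0.5, 77.6% at 1 and 86.5% at 1.5, with 3 false calls. In BiTS against BiTS(mut), over the same 13802 genes, the blocked fit recovered 70.2%, with 47.4%, 76.1% and 82.4% at the 3 sizes and 3 false calls, and the unblocked fit 0 of 198. A shift of 0.3 placed on the glycolysis list was called by camera at the preset correlation in both fits, with no other list called. With an estimated correlation its adjusted p was 0.0304 without the block and 0.117 with it, and with fry 0.0917 and 0.0404. The simulation drew each gene independently, which is close to what the preset correlation assumes. It therefore cannot show how often the preset test calls unchanged lists whose genes vary together.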

Results

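The transcriptomes of OT-I CD8 T cells, whose transgenic T cell receptor recognises the SIINFEKL peptide, were measured 48 h after stimulation with that peptide, in cultures labelled as splenocytes. The cells were treated with BiTS, a bispecific T cell silencer that links LAG-3 to the T cell receptor, with BiTS(mut), or with an isotype control. The series asks how the transcriptional state of activated OT-I cells differs between these 3 treatments. Each group had 2 libraries. The 18 tested dendritic cell markers together held between 1525 CPM (BiTS replicate 2) and 3696 CPM (isotype replicate 1). Other cells of the culture may thus contribute RNA, and the changes below cannot be assigned to the OT-I cells alone. Total gene counts were 13482663 and 10813123 for BiTS replicates 1 and 2, 11635669 and 11104184 for isotype replicates 1 and 4, and 15239077 and 12291548 for BiTS(mut) replicates 1 and 2. Log2 fold changes are given with their standard errors, with 2 libraries per group, and p-values measure only the spread between these samples. In the blocked fit a gene's spread had 2 residual degrees of freedom of its own and 45.95 from the spread shared over all genes. Without the block these were 3 and 3.14. A small p in the blocked fit therefore does not measure how well a gene's own libraries repeat.

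The first principal component, with 65.4% of the variance, separated the libraries with title numbers 1 to 3 from those with 4 to 6 in every group, and the second, with 12.5%, placed BiTS lowest in both sets. Between the sets 7382 of 13996 genes differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 3618 higher and 3764 lower in the second set. Macrophage and monocyte markers had a median log2 fold change of -1.50 and dendritic cell markers of -1.03 in the second set against the first. Ribosome biogenesis genes had a median of 0.43, with 24 of 30 higher, and cholesterol synthesis genes of 0.49, with 19 of 24 higher. With an estimated correlation 0 of 26 lists passed between the sets, and the lowest was an adjusted p = 0.366 with an estimated correlation. Each comparison below is therefore given without and with a block for the set.

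**Figure D1:**
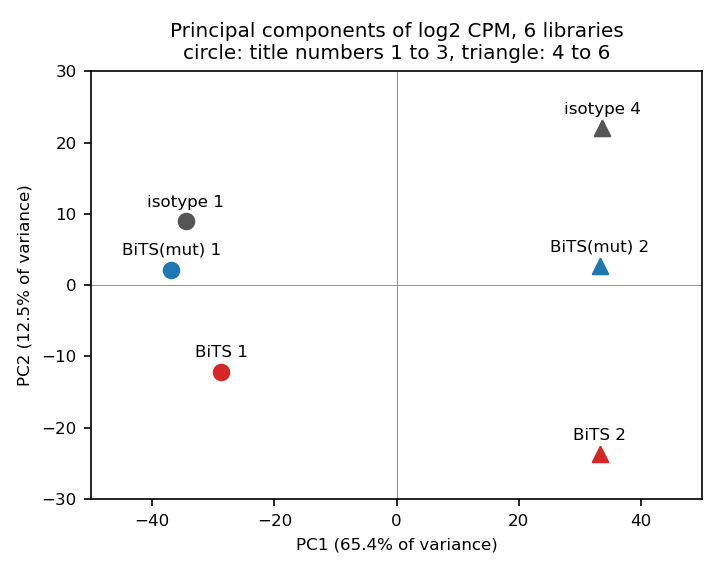
Principal components of log2 CPM, 1 point per library, coloured by group; the horizontal axis carries 65.4% and the vertical axis 12.5% of the variance. Libraries with title numbers 1 to 3 (circles) lie left of 0 and those with 4 to 6 (triangles) right of 0.

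The comparison of BiTS with isotype addresses what BiTS does in these cultures of activated OT-I cells. Ifng, the effector cytokine interferon gamma, was at 45.4 CPM (SD 16.4) in BiTS and 141 CPM (SD 81.0) in isotype, 2.97-fold lower within sets, with a log2 fold change of -1.57 ± 0.10. Prf1, which encodes the pore-forming protein perforin, fell by 1.08 ± 0.10 on the log2 scale. Both were lower in BiTS in both sets, as was the cytokine Il3 (-1.14 ± 0.16). The chemokines Ccl22 (-0.73 ± 0.09) and Ccl17 (-1.03 ± 0.14) also fell, and both stand in the list of dendritic cell markers, whose 18 tested members all had a negative log2 fold change. The proximal signalling genes Plcg1 (0.48 ± 0.08) and Lck (0.41 ± 0.08) rose. With the main filter on low counts, these changes passed the test only with the block for the set. With no such filter the unblocked test called 11 genes.

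Without the block, edgeR's quasi-likelihood test called 0 of 13996 genes, with 176 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. With the block it called 476 genes, 253 higher and 223 lower in BiTS, of which 475 had the same sign in both sets and 44 changed at least 2-fold. The call itself favours genes that agree between the sets, so the shared sign is not separate evidence. The lowest Benjamini-Hochberg adjusted p, for Ifng, was 1.48e-16. Ifng lies on chromosome 10 from 118441047 to 118445892 and Prf1 on chromosome 10 from 61297836 to 61304263 (mm10).

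Among the 19 tested cytokines and chemokines of activated T cells, 9 fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose. Ltb, which encodes lymphotoxin beta, was the member that rose (0.55 ± 0.09), and Tnf was at -0.32 ± 0.10, an adjusted p of 0.0499 by edgeR's quasi-likelihood test. The list's median was -0.40, with an adjusted p = 0.3003 with an estimated correlation. Of the 16 cytotoxic effector genes, 4 fell and 1 rose, and adjusted over the list alone 8 fell and 1 rose (median -0.22, adjusted p = 0.3003 with an estimated correlation). Beside Prf1 these included Serpinb9, an inhibitor of granzyme B (-0.48 ± 0.08), and Gzmb, granzyme B itself (-0.33 ± 0.09), while Gzmc fell by 1.16 ± 0.31 on the log2 scale. Gzmc was at -1.83, -0.43 and -0.39 without BiTS replicate 1, BiTS replicate 2 and isotype replicate 4, and Gzmb at -0.17, -0.53 and -0.13 without BiTS replicate 2, isotype replicate 1 and isotype replicate 4.

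Of the 24 TCR-induced activation genes, 6 fell and 0 rose, and adjusted over the list alone 9 fell (median -0.14, adjusted p = 0.386 with an estimated correlation). Tagap, a GTPase-activating protein of activated T cells, was at -0.63 ± 0.09, and the transcription factors Egr1 and Irf4 at -0.61 ± 0.11 and -0.38 ± 0.08. Of the 18 inhibitory receptor and exhaustion genes, 4 fell, and 5 adjusted over the list alone (median -0.16, adjusted p = 0.3003 with an estimated correlation). These were led by Cd200 (-0.68 ± 0.11), Cd274, which encodes PD-L1 (-0.53 ± 0.09), and Rgs16 (-0.63 ± 0.14), a regulator of G protein signalling that was at -0.39 without isotype replicate 4. Of the 26 genes of the TCR complex and proximal signalling, 6 rose, and adjusted over the list alone 11 rose and 2 fell (median 0.20, adjusted p = 0.335 with an estimated correlation). Beside Plcg1, a phospholipase, and Lck, the kinase that starts receptor signalling, Ptpn22, a phosphatase that restrains it, rose by 0.47 ± 0.08, and Cd8a, the coreceptor chain, by 0.34 ± 0.09 (0.22 without BiTS replicate 1).

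Of the 26 interferon gamma response genes, 7 fell, and adjusted over the list alone 13 fell and 1 rose (median -0.22, adjusted p = 0.3003 with an estimated correlation), among them Ciita, the activator of MHC class II genes (-1.39 ± 0.25), the GTPase Iigp1 (-0.78 ± 0.14) and Gbp2 (-0.36 ± 0.09). Of the 24 type I interferon response genes, 3 fell, and adjusted over the list alone 9 fell and 1 rose (median -0.24, adjusted p = 0.386 with an estimated correlation). They were Usp18 (-0.58 ± 0.14), Oasl2 (-0.55 ± 0.15, -0.32 without BiTS replicate 1) and Oasl1 (-0.32 ± 0.09). Of the 18 dendritic cell markers 7 fell, and 14 adjusted over the list alone (median -0.33, adjusted p = 0.3003 with an estimated correlation). Cd83, a marker of mature dendritic cells that activated lymphocytes also express, was at -0.55 ± 0.09, and Ciita is a member of both this list and the interferon gamma list. Of the 11 macrophage and monocyte markers 0 passed edgeR's quasi-likelihood test, adjusted over all genes or over the list alone, and their median was 0.07.

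Of the 24 genes of the ATF4 and integrated stress response, 5 rose, and 11 adjusted over the list alone (median 0.22, adjusted p = 0.386 with an estimated correlation). Ddit3, the stress transcription factor CHOP, was at 0.51 ± 0.09, Trib3 at 0.50 ± 0.09 and Vldlr, a lipoprotein receptor, at 0.60 ± 0.13. Of the 24 glycolysis genes 4 rose, and 4 adjusted over the list alone (median 0.07, adjusted p = 0.622 with an estimated correlation), among them Pfkm, a phosphofructokinase (0.59 ± 0.09), Pdk1, which restrains entry of pyruvate into mitochondrial oxidation (0.47 ± 0.09), and Aldoc, an aldolase (0.43 ± 0.10). Of the 24 cholesterol synthesis and uptake genes 4 fell, and 7 adjusted over the list alone (median -0.14, adjusted p = 0.395 with an estimated correlation), with Idi1 at -0.50 ± 0.14 and Acat2 at -0.36 ± 0.10. Of the 30 ribosome biogenesis and MYC target genes 2 fell, Nop16 (-0.40 ± 0.10) and Odc1 (-0.33 ± 0.09), and 6 adjusted over the list alone (median -0.15, adjusted p = 0.716 with an estimated correlation). Of the 30 DNA replication genes 1 fell, Rrm2 (-0.31 ± 0.09), with the same count adjusted over the list alone (median -0.07, adjusted p = 0.751 with an estimated correlation). Within sets, the median of ribosome biogenesis genes was -0.003 in the first and -0.30 in the second, and that of DNA replication genes 0.004 and -0.155. Without isotype replicate 4, Idi1 was at -0.13, Odc1 at -0.12 and Nop16 at -0.27, and without isotype replicate 1 Idi1 was at -0.85 and Odc1 at -0.53. Without BiTS replicate 2, Idi1 was at -0.28, Odc1 at -0.21, Nop16 at -0.22, Pdk1 at 0.28 and Aldoc at 0.25.

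These 13 lists were called at the preset correlation in both fits, 3 up and 10 down, and 0 of 26 with an estimated correlation or with fry, whose lowest adjusted p was 0.221 without and 0.123 with the block. Fry's mixed test, for movement in either direction, passed 15 lists with the block and 0 without. Without the block, the lowest was an adjusted p = 0.129 with an estimated correlation, and the count of lists was 8 without BiTS replicate 1 and 8 without isotype replicate 4. Of the 13 lists not called, naive and memory genes had 3 members lower, Actn1 (-0.34 ± 0.08) and Dapl1 (-0.37 ± 0.09) among them, and 1 rose and 3 fell adjusted over the list alone. Anergy genes had 2 higher, Ikzf3 (0.33 ± 0.09) among them, and 2 lower, Dusp2 (-0.37 ± 0.10) and Socs1 (-0.33 ± 0.09), or 4 and 2 adjusted over the list alone. IL-2 and STAT5 targets had Slc2a3, a glucose transporter (0.41 ± 0.09, 0.25 without BiTS replicate 2), and the kinase Pim2 (0.39 ± 0.08) higher and Ccnd2, a cyclin (-0.33 ± 0.08), lower, with the same counts adjusted over the list alone. Amino acid genes had Slc38a2, an amino acid transporter (0.38 ± 0.08), higher and Shmt1 (-0.38 ± 0.10) and Mat2a (-0.35 ± 0.10) lower, with the same counts adjusted over the list alone. Mat2a was at -0.54 and -0.16 without BiTS replicates 1 and 2 and at -0.57 and -0.12 without isotype replicates 1 and 4. Bub1, a spindle checkpoint kinase, rose (0.45 ± 0.09) among mitosis genes, and Pmaip1, a mediator of apoptosis, fell (-0.34 ± 0.09) among p53 targets, where 2 rose and 2 fell adjusted over the list alone. Cd7 (1.34 ± 0.32) and Rora (0.49 ± 0.15) rose among the 7 NK and innate lymphoid markers, with the same count adjusted over the list alone. Oxidative phosphorylation, the unfolded protein response, T helper and Treg genes, B cell markers and stromal markers had 0 members called by edgeR's quasi-likelihood test over all genes, and 0, 2, 1, 1 and 0 adjusted over the list alone. Median, mean and camera's direction differed in sign for 7 of these 13 lists, namely naive and memory, anergy, mitosis, T helper, macrophage, B cell and stromal genes, and for 0 of the 13 that were called.

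Outside the lists, the largest increases among genes that met the naming rule included Endou (1.19 ± 0.26), Tnfrsf8, the activation receptor CD30 (0.97 ± 0.12), Ptpn13, a phosphatase (0.98 ± 0.19), and Mt2, a metallothionein (0.88 ± 0.11). The largest decreases among such genes included Lum, a matrix proteoglycan (-1.78 ± 0.32), Selp, the adhesion receptor P-selectin (-1.35 ± 0.13), Il23a, the p19 subunit of interleukin 23 (-1.22 ± 0.16), Klrc1, the inhibitory receptor NKG2A (-1.09 ± 0.17), Lars2 (-1.22 ± 0.13) and Mir6236 (-1.67 ± 0.20). Lars2 was at -0.63 without isotype replicate 4 and -0.74 without BiTS replicate 2, Mir6236 at -1.10 without isotype replicate 4, and Endou at 0.76 without BiTS replicate 2. Lars2 and Mir6236 were also lower in BiTS(mut) than in isotype (-1.26 and -1.39), so their fall is not particular to BiTS. Both belong to the genes grouped around CT010467.1, whose summed level was highest in isotype replicate 4 (4852 CPM). Ctla2a, Serpinb9, Serpinb6b, Klrc1, Gbp2, Apol7c and Iigp1 belong to gene families with close copies whose reads the counting could have split. Among the fixed genes that passed in neither fit, Lag3 was at 0.08 ± 0.08, Cd3e at 0.15 ± 0.09, Il2ra at -0.09 ± 0.08, Cd69 at -0.13 ± 0.10, Nr4a1 at 0.11 ± 0.08, Myc at -0.08 ± 0.08, Mki67 at 0.09 ± 0.08, Tcf7 at 0.09 ± 0.09 and Pdcd1 at -0.29 ± 0.13. Il2 averaged 0.681 CPM in BiTS and 0.667 CPM in isotype, and a change in it was not detectable at this depth.

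The blocked count was 345, 130, 937, 581, 291 and 306 without BiTS replicates 1 and 2, isotype replicates 1 and 4 and BiTS(mut) replicates 1 and 2, and 0 when libraries were scaled to the spike-in transcripts. Of the 71 called values of the named-gene rule, 22 stayed called in every other blocked setting except spike-in scaling, among them Ifng, Prf1, Il3, Ccl22, Ccl17, Cd83, Cd274, Tnfrsf8, Ltb, Plcg1 and Ddit3, while 41 were lost without BiTS replicate 2, including Lck (0.40 without it), Egr1 (-0.42), Irf4 (-0.30), Cd200 (-0.48) and Gzmb (-0.17), 16 without BiTS replicate 1, including Cd8a (0.22), Usp18 (-0.47) and Tnf (-0.36), 9 without isotype replicate 1, 12 without isotype replicate 4, and 17 and 18 without BiTS(mut) replicates 1 and 2. DESeq2 with the block did not call 32 of the 71, including Endou, Ptpn13, Lars2, Gzmb, Usp18, Idi1 and Rora, and for 3 of the 32, Lum (-1.81), Gzmc (-1.09) and Cd7 (1.42), it gave no adjusted p. Tnf was called in 5 of the 15 blocked settings other than spike-in scaling, Rora in 6, Ikzf3 and Oasl1 in 7, and Socs1, Rrm2, Mat2a and Acat2 in 8.

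**Figure D2:**
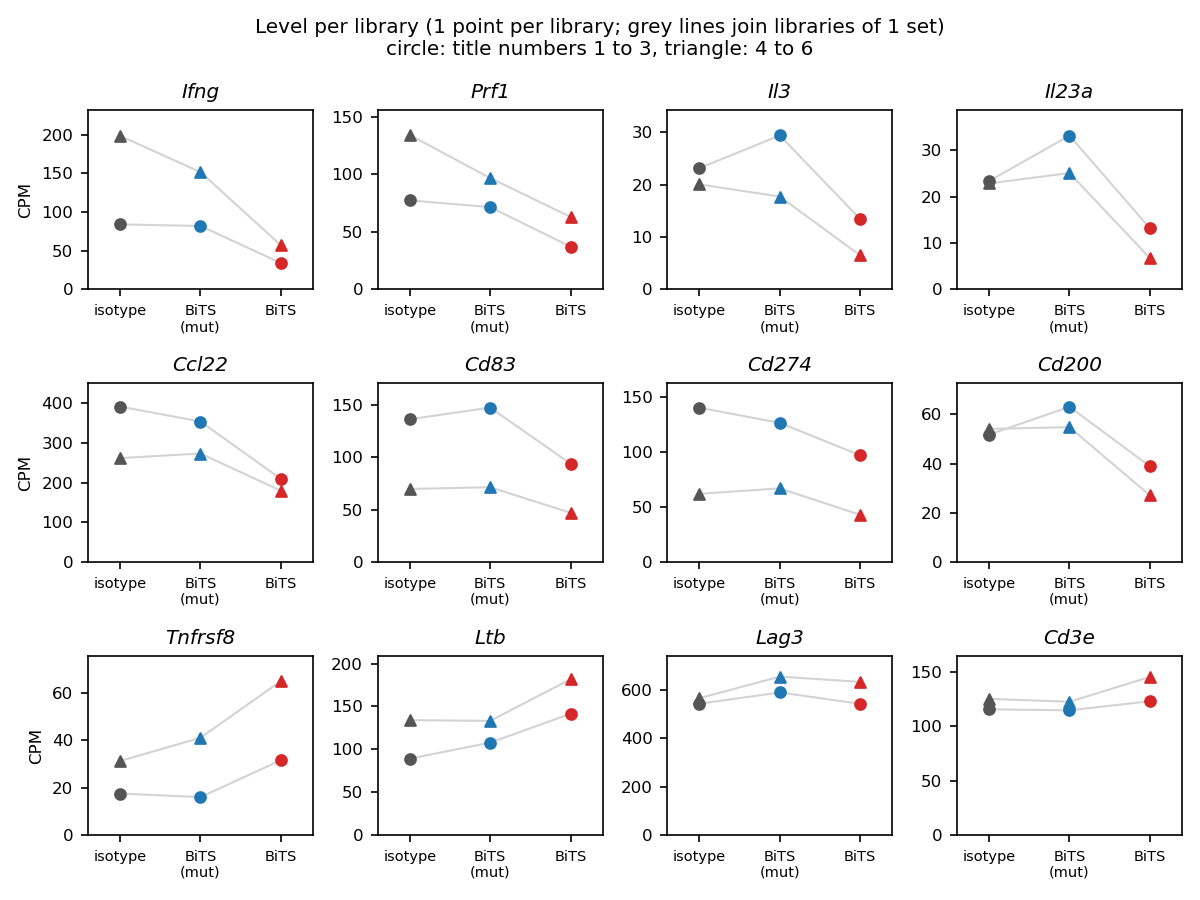
CPM per library for 12 genes named by the rule; the horizontal axis gives the group, and grey lines join libraries of the same set (circles, title numbers 1 to 3; triangles, 4 to 6). Ifng was at 33.9 and 57.0 CPM in the BiTS libraries against 83.9 and 198.5 CPM in the isotype libraries, while Lag3 lay between 542.8 and 655.3 CPM in all 6.

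The comparison of BiTS with BiTS(mut) addresses which differences depend on the feature changed in BiTS(mut), which the labels do not describe. Ifng was 2.54-fold lower in BiTS within sets (-1.35 ± 0.10), and Prf1 fell by 0.78 ± 0.10 on the log2 scale. The cytokine genes Il3 (-1.24 ± 0.16) and Il23a (-1.54 ± 0.15) and the chemokines Ccl22 (-0.68 ± 0.09) and Ccl17 (-0.84 ± 0.14), again dendritic cell list members, were also lower, and Cd40, the costimulatory receptor of antigen-presenting cells, was at -0.89 ± 0.15. With the main filter on low counts, all of these passed the test only with the block for the set. With no such filter the unblocked test called 3 genes.

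Without the block, edgeR's quasi-likelihood test called 0 genes, with 76 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. With the block it called 136 genes, 38 higher and 98 lower in BiTS, all with the same sign in both sets and 17 of them at least 2-fold. Here too the call favours genes that agree between the sets. The lowest Benjamini-Hochberg adjusted p, again for Ifng, was 5.83e-14.

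Of the 19 cytokines and chemokines, 3 fell and 1, Ltb, rose (0.42 ± 0.09), and adjusted over the list alone 9 fell and 1 rose (median -0.29, adjusted p = 0.273 with an estimated correlation). Of the 16 cytotoxic effector genes 3 fell, Prf1, Serpinb6b (-0.34 ± 0.08) and Serpinb9 (-0.31 ± 0.08), and 4 adjusted over the list alone (median -0.17, adjusted p = 0.397 with an estimated correlation). Gzmb was at -0.19 ± 0.09 and Tnf at -0.20 ± 0.10, and neither passed. Of the 24 TCR-induced activation genes 2 fell, Tagap (-0.50 ± 0.09) and Egr2 (-0.76 ± 0.20), and 8 adjusted over the list alone (median -0.12, adjusted p = 0.424 with an estimated correlation). Egr2 was called in 7 of 15 blocked settings. It was not called by limma-voom, with library totals or the stricter filter, or without BiTS replicates 1 and 2 (-0.87 and -0.65) or BiTS(mut) replicates 1 and 2 (-0.98 and -0.53). Of the 18 inhibitory receptor and exhaustion genes 3 fell, Cd200 (-0.83 ± 0.11), Cd274 (-0.50 ± 0.09) and Rgs16 (-0.65 ± 0.14). Adjusted over the list alone 4 fell and 1 rose (median -0.17, adjusted p = 0.273 with an estimated correlation).

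Of the 26 genes of the TCR complex and proximal signalling, Ptpn22 rose (0.34 ± 0.08) and Cd5, an inhibitory coreceptor, fell (-0.33 ± 0.09), and adjusted over the list alone 6 rose and 2 fell (median 0.16, adjusted p = 0.424 with an estimated correlation). Of the 18 dendritic cell markers 6 fell, led by Ccl22, Cd83 (-0.63 ± 0.09) and Ccl17, and 14 adjusted over the list alone (median -0.27, adjusted p = 0.273 with an estimated correlation). Of the 26 interferon gamma response genes 1 fell, Ciita (-1.25 ± 0.25), with the same count adjusted over the list alone (median -0.08, adjusted p = 0.424 with an estimated correlation). Glycolysis had Pfkm (0.37 ± 0.09) and Pdk1 (0.33 ± 0.09) higher, with the same count adjusted over the list alone (median 0.05, adjusted p = 0.778 with an estimated correlation). The ATF4 list had Trib3 higher (0.37 ± 0.09) and Slc7a11, a cystine transporter, lower (-0.68 ± 0.15), with the same counts adjusted over the list alone (median 0.10, adjusted p = 0.778 with an estimated correlation). Ribosome biogenesis genes had 0 members called by edgeR's quasi-likelihood test, also adjusted over the list alone (median -0.06, adjusted p = 0.814 with an estimated correlation). Their median was 0.078 in the first set and -0.176 in the second, and that of glycolysis genes -0.001 and 0.064. Pfkm was at 0.24 without BiTS replicate 2, and Pdk1 at 0.52 and 0.15 without BiTS replicates 1 and 2 and 0.21 without BiTS(mut) replicate 2.

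At the preset correlation 6 lists were called without the block, 1 up and 5 down, and the 10 above with it, 3 up and 7 down. With an estimated correlation or with fry 0 were called in either fit, and the lowest adjusted p with fry was 0.556 without and 0.138 with the block. Fry's mixed test passed 4 lists with the block and 0 without. Without the block, the lowest was an adjusted p = 0.268 with an estimated correlation. Of the 16 lists not called in the blocked fit, naive and memory genes had 3 members lower, Dapl1 (-0.54 ± 0.09) and Actn1 (-0.36 ± 0.08) among them, with the same count adjusted over the list alone, and IL-2 and STAT5 targets had Ccnd2 lower (-0.31 ± 0.08), or 2 rose and 2 fell adjusted over the list alone. The remaining 14 had 0 members called by edgeR's quasi-likelihood test over all genes, and adjusted over the list alone 1 anergy gene, 2 p53 targets and 1 stromal marker fell, 1 B cell marker rose and 1 fell. Median, mean and camera's direction differed in sign for 8 of the 16, namely naive and memory, anergy, DNA replication, amino acid, T helper, macrophage, B cell and stromal genes.

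Outside the lists, Endou (1.31 ± 0.26), Ctla2a, a cysteine protease inhibitor with a close copy (0.99 ± 0.13), and the chemokine receptor Ccr4 (0.77 ± 0.15) rose. Lum (-1.74 ± 0.32), Selp (-0.99 ± 0.13), Apol7c (-1.18 ± 0.24) and Il1b, interleukin 1 beta (-0.998 ± 0.236), fell. Apol7c was at -1.85 and -0.78 without BiTS(mut) replicates 1 and 2, and Il1b at -1.84 and -0.61 without BiTS replicates 1 and 2. Lag3 was at -0.08 ± 0.08, Cd3e at 0.17 ± 0.08, Cd8a at 0.29 ± 0.08, Il2ra at 0.06 ± 0.08, Cd69 at 0.01 ± 0.10, Nr4a1 at -0.07 ± 0.08, Myc at 0.04 ± 0.08, Mki67 at 0.12 ± 0.08, Tcf7 at 0.02 ± 0.09 and Pdcd1 at -0.19 ± 0.13, and none of these 10 passed edgeR's quasi-likelihood test in either fit.

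The blocked count was 100, 65, 361, 435, 25 and 28 without BiTS replicates 1 and 2, isotype replicates 1 and 4 and BiTS(mut) replicates 1 and 2, and 0 when libraries were scaled to the spike-in transcripts. Of the 42 called values of the named-gene rule, 9 stayed called in every other blocked setting except spike-in scaling (Ifng, Ctla2a, Il23a, Il3, Selp, Prf1, Cd200, Ccl22 and Cd83), while 16 and 24 were lost without BiTS replicates 1 and 2, including Ccl17 (-0.57 without replicate 1), and 25 and 31 without BiTS(mut) replicates 1 and 2, including Lum (-1.46 without replicate 1), Cd40 (-0.65 without replicate 2) and Ccr4 (0.64 without replicate 2). DESeq2 with the block did not call 19 of the 42, including Ccr4, Pfkm and Trib3. For 7 of the 19, among them Endou (1.36), Lum (-1.78), Ciita (-1.31), Apol7c (-1.31), Il1b (-1.11) and Egr2 (-0.77), it gave no adjusted p.

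With the block, 106 genes were called in both comparisons with the same sign, 35 higher and 71 lower in BiTS, and 0 with opposite signs (edgeR quasi-likelihood test). Among the shared genes were Ifng, Prf1, Il3, Il23a, Selp, Ccl22 and Cd83 on the lower side and Ltb, Endou, Trib3 and Pfkm on the higher side. Independent lists of these sizes would share 0.69 and 1.56 genes, and 50 simulations of unchanged groups with the same shared libraries called at most 2 genes in a comparison, so their overlap of 0 does not measure what the shared libraries bring. The covariance of the log2 fold changes across genes, which are not independent replicates, was 0.0588 against a simulated mean of 0.0318, a difference of 0.027. Both comparisons use the same BiTS libraries, so part of the overlap may come from them. In a check added after these results were seen, the log2 fold changes of BiTS against isotype in 1 set and against BiTS(mut) in the other, which share no library, correlated at 0.164 and 0.129 over 13996 genes, against -0.03 to 0.034 in 50 simulations of unchanged groups. All these simulations drew each gene independently, while real genes can vary together. Their narrow range therefore cannot show whether unchanged groups would give such a covariance or such correlations. DESeq2 with the block gave an overlap of 40 genes and limma-voom 130, and without the block edgeR, DESeq2 and limma-voom called 0 genes in either comparison.

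The comparison of BiTS(mut) with isotype addresses what the mutated molecule does by itself. Few genes differed: with the block 7 were called, 6 lower and 1 higher, and 6 of the 7 changed at least 2-fold. The lower ones were Lars2, a mitochondrial leucine tRNA synthetase (-1.26 ± 0.13), Mir6236 (-1.39 ± 0.19), CT010467.1, which is annotated as ribosomal RNA (-0.87), and the gene models Gm23935 (-1.44), Gm24270 (-1.89) and Gm24187 (-1.80). The higher one was the pseudogene Gm5786 (1.497). The last 5 fall outside the naming rule and were chosen after their values were seen.

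Without the block edgeR's quasi-likelihood test called 0 genes, with 41 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The 6 lower genes together held 4852 CPM in isotype replicate 4 and 1135 to 2171 CPM in the other 5 libraries. Ifng was at -0.23 ± 0.09, an adjusted p of 0.9997 by edgeR's quasi-likelihood test with the block, Gzmb at -0.14 ± 0.09, Tnf at -0.12 ± 0.10, Lag3 at 0.16 ± 0.08 and Cd8a at 0.05 ± 0.09. This comparison is also the test of whether the BiTS effects against the 2 controls differ, and it called none of the fixed genes. A log2 fold change of Ifng between -0.41 and -0.04 lay within its 95% interval.

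No list member was called over all genes in this comparison. At the preset correlation 5 lists were called without the block, 1 up and 4 down, and 7 with it, namely DNA replication (median -0.07), ribosome biogenesis (-0.09), cholesterol synthesis (-0.10), type I interferon (-0.16) and interferon gamma response genes (-0.09) down and ATF4 (0.13) and TCR complex genes (0.06) up. None passed otherwise: with the block the lowest was an adjusted p = 0.692 with an estimated correlation and 0.252 with fry, and without it 0.822 and 0.998, and fry's mixed test passed 0 lists in either fit. Adjusted over the list alone, 0, 0, 2, 1, 3, 2 and 0 members of the 7 lists passed, and among lists not called 1 cytotoxic effector gene and 1 T helper gene fell and 1 NK marker rose. The median of TCR complex genes was 0.104 in the first set and -0.015 in the second. The count of lists without the block was 9 without isotype replicate 1 and 3 and 11 without BiTS(mut) replicates 1 and 2, and with the block 3 without BiTS(mut) replicate 1. Median, mean and camera's direction differed in sign for 6 of the 19 lists not called. These were the lists of inhibitory receptor and exhaustion genes, anergy, IL-2 and STAT5, unfolded protein response, p53 and T helper genes. The blocked count of genes was 12 without either BiTS replicate, 132 and 15 without isotype replicates 1 and 4, and 9 and 7 without BiTS(mut) replicates 1 and 2, and Mir6236 was not called without isotype replicate 4 (-0.83) or BiTS(mut) replicate 2 (-0.98), and Lars2 was at -0.64 without isotype replicate 4. DESeq2 with the block called neither Lars2 nor Mir6236.

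**Figure D3:**
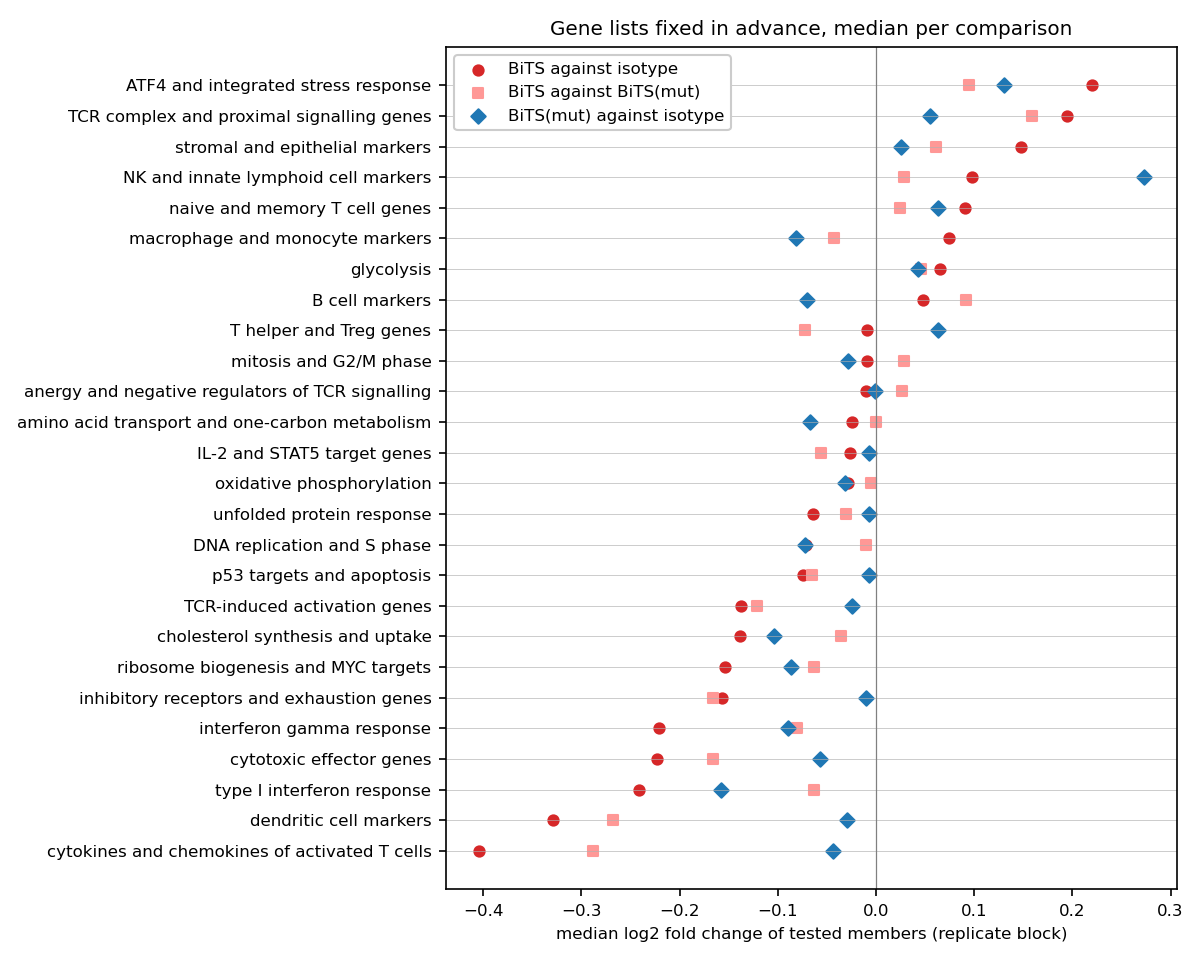
Median log2 fold change of the tested members of each of 26 gene lists in the fit with the block, for the 3 comparisons. Cytokines and chemokines of activated T cells had medians of -0.40 and -0.29 in BiTS against isotype and against BiTS(mut), and -0.04 in BiTS(mut) against isotype.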

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

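The comparison of spike-in shares in this part was made only after the shares were seen. In BiTS(mut) replicate 2 the ERCC spike-in transcripts, which the comparisons leave out, took 7.54% of all counts (95% Wilson interval 7.52% to 7.55%), above the highest isotype library, replicate 4, at 5.38%. The libraries held 25.5 and 18.4 gene counts per spike-in count in BiTS replicates 1 and 2, 23.8 and 17.6 in isotype replicates 1 and 4, and 28.8 and 12.3 in BiTS(mut) replicates 1 and 2.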

How the results depend on the processing

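The combinations of the block with other choices, spike-in scaling and the fit without CT010467.1 and 5 genes grouped with it were chosen only after the results were seen. Counts for BiTS against isotype, BiTS against BiTS(mut) and BiTS(mut) against isotype follow in that order. The unblocked counts of 0, 0 and 0 became 476, 136 and 7 with the replicate block and 11, 3 and 5 with no filter on low counts, and stayed 0 under the other planned tools, scalings and filters and without each library in turn. The unblocked overlap of 0 became 106 with the block. With the block, counts were 160, 53 and 1 by DESeq2 (overlap 40), 295 and 442 in BiTS against isotype and BiTS against BiTS(mut) with only the 4 libraries compared, 14 in BiTS(mut) against isotype with no filter, 44 and 17 at 2-fold or more, 0 in all 3 without the block, and 0, 0 and 1 with spike-in scaling, which gave a median of all genes of 0.053, 0.178 and -0.121 against -0.005, 0.001 and 0; the cause was not tested. With library totals alone the split in BiTS against isotype was 165 higher and 246 lower, against 253 and 223. Without CT010467.1 and the 5 genes grouped with it 0 genes were called in BiTS(mut) against isotype. Leaving out 1 library gave blocked counts of 130 to 937, 25 to 435, and 7 to 132. Lists called were 13, 6 and 5 without the block, 8 to 12, 5 to 7 and 3 to 11 leaving out 1 library (7 to 12, 1 to 5 and 0 to 4 of them among the lists called with all libraries), and 10 in BiTS against BiTS(mut) with the block. With the block they were 13, 10 and 7, 11 to 15, 7 to 11 and 3 to 10 leaving out 1 library (10 to 13, 6 to 10 and 3 to 6 shared), and 6 in BiTS against BiTS(mut) without it. With an estimated correlation or fry's directional test 0 lists were called in the fits of all 6 libraries with and without the block, the only ones these were run on. Fry's mixed test passed 0 lists without the block and 15, 4 and 0 with it. Among the 153 named values, the block turned 115 from not called to called and changed the sign of 1 that was called in neither fit. Over all genes of the naming rule, 115 values were called with the block, 31 of them in all 15 blocked settings other than spike-in scaling, 84 were not called in at least 1, and 115 kept their sign in each setting that held the gene. The 4 values of Lars2 and Mir6236 are absent where their group is taken out, and Mir6236 in BiTS against isotype counts among the 84 only for that. Of the 153 named values, 115 were called with the block. Of these, 14 had the opposite sign in 20 leave-one-out values without the block, since dropping a library leaves the arms unequal between the sets. Values not called with the block changed sign as well. There were 8 and 6 without BiTS replicates 1 and 2, 3 and 9 without isotype replicates 1 and 4, and 11 and 6 without BiTS(mut) replicates 1 and 2. The ranges of 12 of these 14 leaving out 1 library were, in BiTS against isotype, -0.741 to 0.036 for Dapl1, -1.24 to 0.177 for Cd274, -0.924 to 0.217 for Acat2, -0.852 to 0.234 for Oasl1, -0.771 to 0.073 for Gbp2, -1.126 to 0.454 for Pmaip1, -1.135 to 0.017 for Cd83 and -0.029 to 0.893 for Rora, and in BiTS against BiTS(mut) -0.952 to 0.3 for Serpinb6b, -0.801 to 0.12 for Serpinb9, -1.173 to 0.075 for Cd274 and -1.535 to 0.125 for Slc7a11. Where leaving out a library left 1 in an arm, it was assumed to vary like the others. A gene such as Il2, near 1 CPM or less, was limited by depth.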

Other observations

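The tests in this part were chosen only after the results they measure were seen, except for the line-ups of the arms and the first version of the test for fewer antigen-presenting cells, whose predictions were written before. Heat shock genes, outside the lists and chosen after their values were seen, moved unevenly. In the blocked fit Hspa1a and Hspa1b, near-identical copies whose reads can be shared, were higher in BiTS than in isotype (log2 fold change 1.66 ± 0.16 and 1.47 ± 0.16) and than in BiTS(mut) (1.02 ± 0.14 and 0.84 ± 0.14). The chaperone genes Dnajb1 (0.26 ± 0.09), Hsph1 (-0.04 ± 0.10), Hsp90aa1 (-0.08 ± 0.08), Hspa8 (-0.03 ± 0.08), Hspb1 (1.62 ± 0.79), Dnaja1 (-0.14 ± 0.09), Hspe1 (-0.04 ± 0.08) and the cochaperone gene Bag3 (-0.37 ± 0.13) did not pass edgeR's quasi-likelihood test in BiTS against isotype.

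The libraries with title numbers 1 to 3 differed from those with 4 to 6 in every arm. Macrophage and monocyte markers were lower in the second set by a median of -1.495 (95% bootstrap interval over genes -1.72 to -1.09) and dendritic cell markers by -1.03 (-1.25 to -0.82), so fewer antigen-presenting cells in the second set is a candidate explanation for these markers. The median of ribosome biogenesis genes exceeded that of TCR complex genes by 0.473 (0.17 to 0.69). If a larger share of T cells raises both lists alike, this argues against it as the whole cause of the higher ribosome biogenesis genes. The argument is weak, since the bootstrap intervals take genes as independent of each other and leave out the spread between libraries. The labels name no batch, and apart from these cell shares no biological explanation was tested.

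Of the 18 dendritic cell markers, 7 fell in BiTS against isotype and 6 against BiTS(mut) in the blocked fit, and the list was called by camera only at the preset correlation (adjusted p = 0.3003 and 0.273 with an estimated correlation). If only these cells express the markers, a uniform loss of antigen-presenting cells as the whole cause is argued against by the scatter of the 18 markers around their common log2 fold change, with a chi-square per degree of freedom of 6.16 (p = 1.19e-14, common value -0.34, 17 degrees of freedom) against isotype and 6.01 (p = 3.56e-14, -0.33) against BiTS(mut). The chi-square also takes the markers as independent of each other. A partial loss stays open, since 386 genes at least 2-fold lower in the second set had medians of -0.15 and -0.13 in these comparisons, and T cells may express some of the markers. Macrophage and monocyte markers showed no matching fall. Their mean log2 CPM in the first and second set was 4.07 and 2.83 in BiTS, 4.07 and 2.87 in isotype, and 4.10 and 2.76 in BiTS(mut). Lower maturation of antigen-presenting cells is only a weak hypothesis. Outside the dendritic cell list, 8 maturation genes lay below 9 lineage genes by -0.132 (permutation of genes, two-sided, p = 0.0467) and -0.212 (p = 0.0114). Values of several of the 8, such as Cd40 and Il12b, had been seen. T cells may express some of the 8 as well, so the difference cannot tell lower maturation from a change in T cells or in the mix of antigen-presenting cells. Both tests replace first versions that were also run and pointed the same way: the 386 genes' median exceeded the marker list's by 0.181 (0.08 to 0.37) and 0.136 (0.06 to 0.50), and 14 maturation genes lay below 13 lineage genes, list members included, by -0.24 (permutation p = 0.00352) and -0.435 (p = 0.00053). The fall of those list members raised the question, so the first maturation version adds no support for lower maturation.

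The summed level of 6 genes grouped as possible carriers of ribosomal RNA reads was highest in isotype replicate 4. That library alone did not drive the calls of BiTS against isotype, since 581 genes were called without it in the blocked fit, 313 of them among the 476. Whether such reads account for the calls of BiTS(mut) against isotype stays open: without the 6 genes of the ribosomal RNA group 0 genes were called, but these 6 are 6 of the 7 calls, so taking them out nearly fixes that count. Of that group only CT010467.1 is annotated as ribosomal RNA, and the link of the others to such repeats is background knowledge that was not tested by sequence.

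The arms of the second set can be lined up with those of the first in 6 ways, too few for a share under 0.05, and each line-up is a split of the same libraries. In BiTS against isotype the real split called 476 genes and the highest other 148, so 1 of 6 called as many. In BiTS against BiTS(mut) the real split called 136 genes, and the split that exchanges isotype and BiTS(mut) in the second set called 189, so 2 of 6 called as many. That split, which also gave the 148, leaves the BiTS libraries in place, so it cannot tell a BiTS effect from chance. The splits that move BiTS called 0 to 5 genes in BiTS against isotype and 0 in BiTS against BiTS(mut). In BiTS(mut) against isotype the real split called 7 and the highest other 5, so 1 of 6 called as many.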
